A study of Mus musculus with 12 samples.

How the data were processed

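Gene expression was measured on Affymetrix arrays in 12 samples of mouse total RNA, 3 biological replicates in each of 4 groups. Per the labels, RNA was extracted with TRIzol, and biotin-labelled cDNA was made from 300 ng of total RNA with the Ambion WT Expression kit. The deposited table holds 35556 probe sets per array as log2 intensities that the authors had normalized between arrays. The method of normalization and the software are not given in the sources used here. The base of the logarithm was read from the values, which ran from 1.11 to 13.48. A natural logarithm would put the brightest probe set at 714401, above the 16-bit scanner limit of 65535. The array distributions were alike but not identical, and no 2 columns were the same. The values were used as deposited, and no column of values was left out.

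Probe sets were assigned to genes with the array annotation, and symbols were matched by Entrez ID to a RefSeq gene table. Of the probe sets, 21789 carried exactly 1 gene symbol and were used, 1621 carried several and 12146 had no symbol, and both of the latter kinds were left out. The Entrez ID was found in the RefSeq table for 21698 of the probe sets used. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays stood for the gene, which left 19938 genes. No filter on dim genes was applied. No detection calls were used, so differences that reach values near background are imprecise, with standard errors that cover the spread of replicates alone, and the number of arrays limits the precision of every comparison.

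A linear model of the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and empirical Bayes moderation that added 4.88 prior degrees of freedom. The 6 comparisons between groups were contrasts of this fit. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 19938 genes, and counts of genes changed at least 2-fold also needed an absolute log2 fold change of 1 or more. Fold changes are given on the log2 scale with the moderated standard error. The words rose and fell mean that the first group named in a comparison was higher or lower than the second and that the difference passed this test. Without blocks or pairs in the labels, the arrays were treated as unpaired.

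Gene lists for fat cell functions, for other cell types that tissue or differentiating cultures could hold, and for general cell states were tested with camera in limma, with an inter-gene correlation of 0.01. There were 33 lists with 568 entries, of which 519 were measured, and p-values were adjusted over the 33 lists within each comparison. Camera asks whether a list shifted relative to all other genes. For each list the number of members that rose or fell is given as adjusted over all genes and as adjusted over the list alone, and the camera p is also given with a correlation estimated for each list. Genes set apart in a group were those called in the same direction, at least 2-fold, against each of the other 3 groups. The distance of a model to eWAT was the root mean square log2 difference between an array of the model and the mean of the eWAT arrays, and models were compared by a two-sided exact permutation test, for which 0.1 is the smallest p that 3 against 3 arrays can give.

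Except where an addition is named, the groups, comparisons, tests, gene lists, alternative settings and the rule for naming genes were fixed before the data were examined. Distances over the fibroblast and matrix list and the fatty acid and triglyceride synthesis list were not in that plan and were added later. The text could name, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose arrays did not overlap (clone names, gene models, receptor families and immunoglobulin segments left out), the 3 members of each list with the largest rise and the 3 with the largest fall among those called, and 15 adipocyte, stem cell and sex-linked genes whatever their result. For genes set apart in a group it could name the 10 with the largest smallest difference. Genes named outside this rule are said to have been chosen after their values were seen.

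The alternative settings were quantile normalization, centring of each array on its median or on the mean of the reference genes, leaving out the dimmest 33.3% of genes, the mean of a gene's probe sets in place of the brightest, all probe sets tested as such, only the arrays of the groups compared, the replicate number as a block, array weights, a trended and robust variance, limma treat against a log2 fold change of 1, fry in place of camera, an estimated correlation, and leaving out each array in turn. Centring on the reference genes without Hprt was added after Hprt was seen near background in 1 group. The fit was tested on simulated data drawn from each gene's mean and residual SD, with known changes put into 50 genes at each of 4 sizes, and into 1 list, in the ES arrays. It recovered 44 of 50 genes at a true log2 change of 0.5, 49 at 1, 50 at 1.5 and 50 at 2, called 13 unchanged genes among 224, and called the 1 list that had been shifted and no other. Genes were drawn independently and few were changed. The simulation therefore could not test list calls where members are correlated or where many genes change, as in the real arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.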

Results

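Transcript levels were measured in 12 arrays of mouse RNA, 3 for each of 4 groups. In 3 groups adipocytes had been made in culture. They came from 3T3-L1 cells, an immortal mouse fibroblast line long used as a model of fat cell differentiation, from primary mouse embryonic fibroblasts (PMEF), and from mouse embryonic stem (ES) cells. The fourth group was tissue from healthy wild-type mice that the labels call eWAT, the usual abbreviation of epididymal white adipose tissue. The arrays were alike in spread, with medians over all probe sets between 5.84 and 5.98 on the log2 scale. Over the genes analysed, the medians of the 3T3-L1 arrays were 6.11 to 6.12, against 6.31 to 6.35 in the other arrays. Across genes, which are not independent replicates, Pearson correlations were 0.989 to 0.994 between arrays of 1 group and 0.920 to 0.968 between arrays of different groups.

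The series title asks how fat cells made in culture compare with fat tissue. By root mean square difference over genes of fat cell identity, ES adipocytes lay nearest to eWAT and 3T3-L1 adipocytes farthest from it. The distance to eWAT over the 23 measured genes of the adipocyte list was 2.41 ± 0.05 in 3T3-L1, 1.75 ± 0.05 in PMEF and 1.02 ± 0.02 in ES adipocytes (root mean square log2 difference, mean ± SD, n = 3 arrays). Large differences weigh most in this measure. The SDs cover only the spread between arrays of a group. Cell origin cannot be told apart from other differences in line or culture between the groups. Against eWAT, Rbp4, Lep and Pck1 were at -6.85, -5.92 and -4.79 in 3T3-L1 and at -3.14, -4.69 and -4.52 in PMEF adipocytes. In ES adipocytes they were at 0.47, -3.86 and -1.03. The list as a whole did not shift between PMEF and 3T3-L1 adipocytes (camera adjusted p = 0.878). Distances over the matrix and synthesis lists were added outside the plan. Over the 20 fibroblast and matrix genes, PMEF adipocytes were the farthest at 1.86 ± 0.06, against 1.57 ± 0.05 in 3T3-L1 and 0.91 ± 0.02 in ES adipocytes. Over the 21 genes of fatty acid and triglyceride synthesis the distances were 1.67 ± 0.02 in 3T3-L1, 1.47 ± 0.06 in PMEF and 1.38 ± 0.03 in ES adipocytes. Over all 19938 genes they were 0.921 ± 0.0038, 0.762 ± 0.01 and 0.742 ± 0.0035 in the same order. Exact permutation tests gave p = 0.1 for 11 of the 12 pairs of models, the smallest value that 3 against 3 arrays allow (0.109 after adjustment over the 12 tests). For PMEF against ES on the synthesis genes they gave an exact p = 0.2. With arrays centred on the reference genes, the order of PMEF and ES over all genes turned, to 0.763 and 0.893. Those genes include Hprt, which was near background in ES adipocytes. That centring moved the median difference of ES adipocytes from eWAT by 0.499, against -0.017 without Hprt. In the plot of principal components the arrays of each group fell together, and the first 3 components held 48%, 31.8% and 14.3% of the variance.

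**Figure D1:**
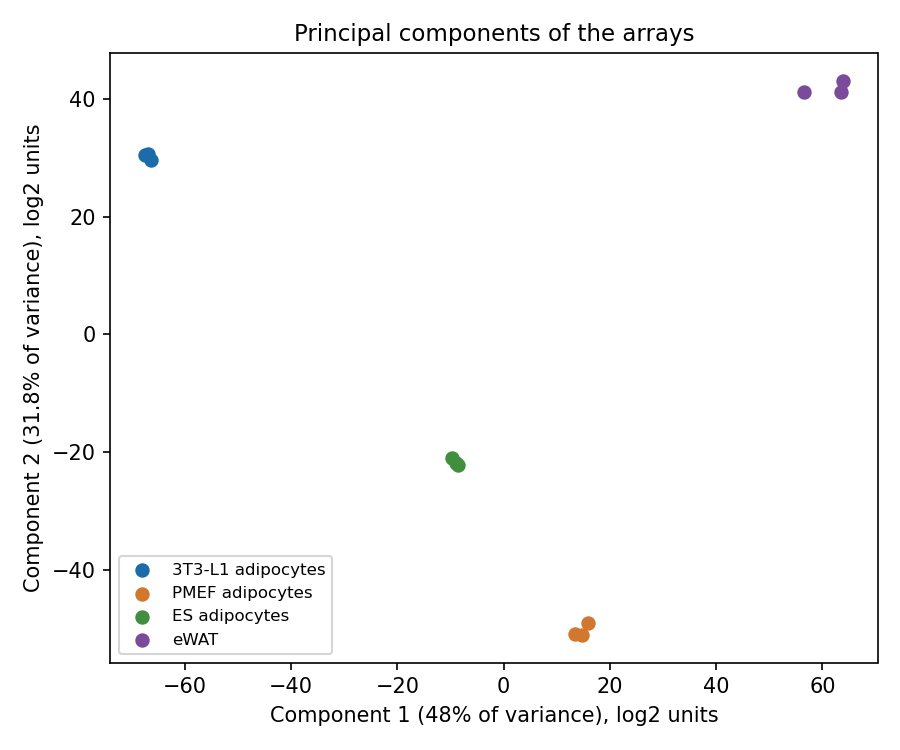
Principal components of the 12 arrays over 19938 genes, with component 1 (48% of the variance) on the horizontal axis and component 2 (31.8%) on the vertical axis, both in log2 units. Each point is 1 array, coloured by group, and the 3 arrays of every group lie close together.

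The first comparison asked how the 3T3-L1 model differs from adipose tissue. Some genes of the hormone and metabolic output of fat were much lower in the cultured cells. Lep, which encodes leptin, fell by 5.92 ± 0.26 on the log2 scale (SE, n = 3 per group), a 60.7-fold difference. The retinol carrier Rbp4 fell by 6.85 ± 0.11, and Pck1, the enzyme that supplies glycerol for triglyceride, fell by 4.79 ± 0.17. Transcripts of class II antigen presentation and blood vessel lining were also far lower.

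In the adipocyte list 15 of 23 genes fell and 2 rose (16 and 2 adjusted over the list alone) in 3T3-L1 adipocytes (camera adjusted p = 5.89e-06, but adjusted p = 0.232 with an estimated correlation). The regulators were unequally affected, with Cebpa at -2.87 ± 0.11 and Pparg at -0.64 ± 0.08. Adipoq (adiponectin) was at -0.95 ± 0.07, Retn (resistin) at -1.12 ± 0.07, the lipid droplet coat gene Plin1 at -1.14 ± 0.08, and Slc2a4, the insulin-responsive glucose transporter, at -0.51 ± 0.09. Fabp5 rose by 1.65 ± 0.13. Fabp4, the main fatty acid carrier of fat cells, was at -0.15 ± 0.06 and did not pass (adjusted p = 0.0559). It passed without PMEF array 1 (0.0447), and also with quantile normalization (0.0108), a trended variance (0.00547), the dimmest 33.3% of genes left out (0.0292) or arrays centred on the reference genes (0.000108, and 0.000201 without Hprt).

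In fatty acid and triglyceride synthesis 16 of 21 genes fell and 4 rose (the same adjusted over the list alone, camera adjusted p = 1.1e-06, but adjusted p = 0.156 with an estimated correlation). Mlxipl, a glucose-sensing regulator, fell by 2.99 ± 0.08, and the enzymes Elovl6 and Acly were at -2.50 ± 0.07 and -2.49 ± 0.09, while the desaturase Fads2 rose by 1.70 ± 0.09. In cholesterol synthesis 14 of 18 genes rose and 2 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.000534, but adjusted p = 0.358 with an estimated correlation), led by Msmo1 at 2.64 ± 0.08 and Sqle at 2.52 ± 0.11. In the thermogenic and beige list 11 of 19 genes fell and 3 rose (the same adjusted over the list alone, camera adjusted p = 0.0206, but adjusted p = 0.359 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, fell by 3.87 ± 0.47 and Cidea was at -3.13 ± 0.13, but Elovl3 rose by 5.09 ± 0.28 and the mitochondrial regulator Ppargc1a by 2.51 ± 0.09.

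Markers of vessel lining and of antigen-presenting cells were low in 3T3-L1 adipocytes. In the endothelial list 20 of 20 genes fell (the same adjusted over the list alone), with a median of -3.65 (camera adjusted p = 3.36e-18, and 0.00866 with an estimated correlation). Emcn was at -6.17 ± 0.18 and Cdh5, the cadherin of vessel junctions, at -5.94 ± 0.11. In class II antigen presentation 7 of 8 genes fell (the same adjusted over the list alone), with H2-Aa at -7.39 ± 0.15 (camera adjusted p = 5.89e-06, and 0.0164 with an estimated correlation). H2-Aa lay near background in each model, at 3.81 to 3.93, so its falls are rough in size. In the macrophage list 20 of 21 genes fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 1.95e-12, but adjusted p = 0.232 with an estimated correlation). Lyz2 was at -6.36 ± 0.20 and C1qb at -5.63 ± 0.24, while the lysosomal gene Cd68 rose by 0.93 ± 0.19.

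Connective tissue genes were lower as well. In the fibroblast and matrix list 13 of 20 genes fell and 5 rose (the same adjusted over the list alone, camera adjusted p = 0.00206, but adjusted p = 0.232 with an estimated correlation), and in the preadipocyte and progenitor list 10 of 15 genes fell and 2 rose (the same adjusted over the list alone, camera adjusted p = 0.000339, but adjusted p = 0.232 with an estimated correlation). The matrix proteoglycan Lum fell by 3.87 ± 0.08, and Cd34, a surface marker of progenitors and vessels, fell by 5.42 ± 0.10. In the smooth muscle list 9 of 13 genes fell and 3 rose (the same adjusted over the list alone), with Myl9 at -4.11 ± 0.16 (camera adjusted p = 0.000936, but adjusted p = 0.232 with an estimated correlation). In the interferon response 16 of 16 genes fell (the same adjusted over the list alone), with a median of -1.81 and the RNA sensor Ifih1 at -3.56 ± 0.15 (camera adjusted p = 1.97e-06, but adjusted p = 0.358 with an estimated correlation). In the cell cycle list 15 of 23 genes rose and 1 fell (the same adjusted over the list alone), with Mcm2 at 2.54 ± 0.09 and Cdk1 at 1.42 ± 0.08 (camera adjusted p = 0.000321, but adjusted p = 0.264 with an estimated correlation). In the inflammatory list 12 of 19 genes fell and 5 rose (12 and 6 adjusted over the list alone, camera adjusted p = 0.0346, but adjusted p = 0.365 with an estimated correlation). The eosinophil attractant Ccl11 fell by 4.60 ± 0.12, and Lcn2, an acute phase protein, rose by 5.46 ± 0.24. Hox genes went down more often than up, in that 16 of 37 genes fell and 7 rose (the same adjusted over the list alone), with Hoxc8 at -5.11 ± 0.09 (camera adjusted p = 0.0305, but adjusted p = 0.359 with an estimated correlation).

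In total 10628 of 19938 genes changed between 3T3-L1 adipocytes and eWAT, 6146 higher and 4482 lower. At least 2-fold changes numbered 2899, 1207 higher and 1692 lower. The arrays did not overlap for 11774 genes, where chance would give 10% of all genes, and 16 of 33 gene lists shifted, 2 up and 14 down. The share of higher calls, 57.8%, was 27.6% with arrays centred on the reference genes (median shift -0.276) and 32.6% without Hprt among them (-0.226). The thermogenic call was lost without eWAT array 1 (adjusted p = 0.0554) and on the reference genes (0.124, and 0.0991 without Hprt). The Hox call was lost without eWAT array 1 (0.0642), on the reference genes (0.0595, and 0.0581 without Hprt) and with quantile normalization (0.105). Its median turned from -0.09 to 0.004 with quantile normalization and to 0.001 with arrays centred on their medians, where the call was kept (0.0233). The inflammatory call was lost without eWAT array 3 (0.061) and on the reference genes (0.305, and 0.271 without Hprt).

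The second comparison set PMEF adipocytes against eWAT. Fibroblast, mesothelial and imprinted genes were high in these embryonic cells after differentiation. The matrix gene Tnc, the mesothelial gene Upk1b and the fetal growth factor Igf2 rose by 3.67 ± 0.16, 4.13 ± 0.12 and 4.23 ± 0.15 (log2, SE, n = 3 per group). Adipocyte genes were lower than in tissue, with Lep at -4.69 ± 0.26 and Pck1 at -4.52 ± 0.17.

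In the adipocyte list 18 of 23 genes fell and 1 rose (19 and 1 adjusted over the list alone) in PMEF adipocytes (camera adjusted p = 2.02e-09, and 0.0488 with an estimated correlation). Rbp4 was at -3.14 ± 0.11, Slc2a4 at -1.64 ± 0.09, Pparg at -0.93 ± 0.08, Cebpa at -0.76 ± 0.11, Plin1 at -0.82 ± 0.08 and Adipoq at -0.46 ± 0.07, and Fabp5 rose by 1.36 ± 0.13. Fabp4 fell by 0.20 ± 0.06 (adjusted p = 0.0177). That call was lost without PMEF array 2 (0.0617) or 3 (0.0545), with quantile normalization (0.0502), with arrays centred on their medians (0.0604) or on the reference genes without Hprt (0.0865), and with only the arrays of the 2 groups (0.082).

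In fatty acid and triglyceride synthesis 17 of 21 genes fell and 2 rose (17 and 3 adjusted over the list alone, camera adjusted p = 5.04e-08, and 0.0488 with an estimated correlation). Mogat1 was at -3.18 ± 0.16 and Acacb, a carboxylase of fatty acid metabolism, at -2.81 ± 0.09, while Fads2 rose by 2.05 ± 0.09. In branched-chain amino acid breakdown 16 of 17 genes fell (the same adjusted over the list alone), with a median of -0.99 (camera adjusted p = 4.13e-11, but adjusted p = 0.0578 with an estimated correlation). Ivd and Mccc1, both enzymes of leucine breakdown, were at -2.05 ± 0.09 and -1.76 ± 0.09. In cholesterol synthesis 16 of 18 genes rose and 1 fell (16 and 2 adjusted over the list alone, camera adjusted p = 2.57e-07, but adjusted p = 0.157 with an estimated correlation), led by Hsd17b7 at 2.28 ± 0.10. In the thermogenic list 9 of 19 genes fell and 4 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.0394, but adjusted p = 0.449 with an estimated correlation). Cidea was at -4.54 ± 0.13, the brown fat regulator Ebf2 at -2.92 ± 0.10 and Ucp1 at -1.69 ± 0.47, and Elovl3 rose by 4.96 ± 0.28.

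In the mesothelial list 13 of 13 genes rose (the same adjusted over the list alone) in PMEF adipocytes, with a median of 1.33 (camera adjusted p = 4.34e-08, and 0.00443 with an estimated correlation). In the fibroblast and matrix list 19 of 20 genes rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 4.84e-12, and 0.0112 with an estimated correlation). In the imprinted growth list 14 of 14 genes rose (the same adjusted over the list alone), with a median of 2.41 (camera adjusted p = 4.13e-11, and 0.00443 with an estimated correlation). The mesothelial Upk3b rose by 3.38 ± 0.16, the collagen cross-linking enzyme Lox by 3.31 ± 0.08, and the imprinted genes Dlk1 and Mest by 4.56 ± 0.12 and 3.37 ± 0.12. In the cell cycle list 21 of 23 genes rose and 1 fell (the same adjusted over the list alone), with Cdk1 at 1.91 ± 0.08 (camera adjusted p = 7.29e-08, but adjusted p = 0.0934 with an estimated correlation). In the smooth muscle list 9 of 13 genes rose and 2 fell (the same adjusted over the list alone), with Actg2 at 2.27 ± 0.12 and Synpo2 at -1.61 ± 0.10 (camera adjusted p = 0.0415, but adjusted p = 0.416 with an estimated correlation). Large single rises included Reg1, a secreted lectin first known from the pancreas, at 7.12 ± 0.13, the angiotensin receptor Agtr2 at 6.45 ± 0.20, and Xist, the RNA that silences an X chromosome in female cells, at 6.14 ± 0.09.

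Markers of vessel lining and of antigen-presenting cells were low in the PMEF cultures too. In the endothelial list 19 of 20 genes fell (the same adjusted over the list alone), with Cdh5 at -5.48 ± 0.11 (camera adjusted p = 3.31e-19, and 0.00443 with an estimated correlation). In class II antigen presentation 7 of 8 genes fell (the same adjusted over the list alone), with Cd74 at -6.82 ± 0.18 (camera adjusted p = 2.27e-07, and 0.00443 with an estimated correlation). In the macrophage list 21 of 21 genes fell (the same adjusted over the list alone), with the receptor Adgre1 at -4.60 ± 0.27 (camera adjusted p = 1.6e-16, but adjusted p = 0.139 with an estimated correlation).

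Between PMEF adipocytes and eWAT 9225 genes changed, 4924 higher and 4301 lower. At least 2-fold changes numbered 2068, 980 higher and 1088 lower. The share of higher ones was 50.1% with arrays centred on their medians and 51.6% on the reference genes without Hprt. The arrays did not overlap for 10351 genes, against 10% by chance, and 14 of 33 lists shifted, 6 up and 8 down. The thermogenic call was lost without eWAT array 1 (adjusted p = 0.0798) and without the dimmest 33.3% of genes (0.133). The smooth muscle call was lost without PMEF array 1 (0.0734), eWAT array 2 (0.0561) or eWAT array 3 (0.0669), without the dimmest genes (0.0923), with quantile normalization (0.0602), and with arrays centred on their medians (0.0605) or on the reference genes without Hprt (0.0583).

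The third comparison set ES adipocytes against eWAT. Here some genes of fat cells were near tissue level and others were not. Cebpa (0.18 ± 0.11, adjusted p = 0.19), Pparg (-0.17 ± 0.08, 0.105) and Fabp4 (-0.08 ± 0.06, 0.342) did not pass the test, and Rbp4 rose by 0.47 ± 0.11 (log2, SE, n = 3 per group). Lep still fell by 3.86 ± 0.26 and Pck1 was at -1.03 ± 0.17. Mesothelial and imprinted genes rose, and markers of vessel lining and class II antigen presentation were far below tissue.

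In the adipocyte list 13 of 23 genes fell and 5 rose (14 and 5 adjusted over the list alone) in ES adipocytes, with a median of -0.23 (camera adjusted p = 0.0267, but adjusted p = 0.425 with an estimated correlation). Differences were small for Retn (-0.36 ± 0.07), Slc2a4 (-0.41 ± 0.09), Adipoq (-0.23 ± 0.07) and Plin1 (-0.23 ± 0.08). The regulator Klf15 fell by 1.39 ± 0.10, while the lipid droplet gene Cidec rose by 0.30 ± 0.07 and Fabp5 by 1.88 ± 0.13. With arrays centred on the reference genes, Hprt included, the small values turned, to 0.33 for Pparg, 0.42 for Fabp4, 0.27 for Adipoq, 0.14 for Retn, 0.27 for Plin1 and 0.09 for Slc2a4, and Cebpa passed (0.67). The Plin1 call was lost without ES array 1 (adjusted p = 0.0505), 2 (0.0599) or 3 (0.0756) or eWAT array 1 (0.109) and with only the arrays of the 2 groups (0.0585), and the Adipoq call without ES array 3 (0.0528). Pparg passed without eWAT array 1 (0.0483), with quantile normalization (0.00198) and with a trended variance (0.0459).

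In fatty acid and triglyceride synthesis 12 of 21 genes fell and 5 rose (14 and 6 adjusted over the list alone, camera adjusted p = 0.000226, but adjusted p = 0.216 with an estimated correlation). Elovl6 was at -3.48 ± 0.07 and Thrsp, a lipogenic gene induced by thyroid hormone, at -2.38 ± 0.11, and Fads2 rose by 1.66 ± 0.09. In branched-chain amino acid breakdown 10 of 17 genes fell and 3 rose (the same adjusted over the list alone), from Ivd at -1.67 ± 0.09 to Bckdhb at 1.20 ± 0.08 (camera adjusted p = 0.00448, but adjusted p = 0.425 with an estimated correlation). In the thermogenic list 12 of 19 genes fell and 4 rose (the same adjusted over the list alone, camera adjusted p = 0.00529, but adjusted p = 0.339 with an estimated correlation). Cidea was at -3.06 ± 0.13, and Elovl3 rose by 5.06 ± 0.28 and the muscle-type cytochrome oxidase gene Cox7a1 by 2.15 ± 0.15. Ucp1 was at -1.02 ± 0.47 and did not pass (adjusted p = 0.0902), but passed without eWAT array 3, at -1.56 (0.00979).

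In the neuronal list 17 of 19 genes rose (the same adjusted over the list alone) in ES adipocytes (camera adjusted p = 3.71e-05, but adjusted p = 0.425 with an estimated correlation). The intermediate filament gene Ina rose by 1.87 ± 0.15 and the migration gene Dcx by 1.74 ± 0.16, to means of 6.76 and 5.78 on the log2 scale. In the neural progenitor and glial list 6 of 13 genes rose and 2 fell (the same adjusted over the list alone), a shift that did not pass camera (adjusted p = 0.0828), and Fabp7, a fatty acid carrier of neural tissue, rose by 4.83 ± 0.17. In the pluripotency list 7 of 20 genes rose and 2 fell (the same adjusted over the list alone), which did not pass either (camera adjusted p = 0.236). The central stem cell factor Pou5f1 stood at 4.21 against 3.64 in eWAT (0.57 ± 0.10). In the mesothelial list 12 of 13 genes rose (the same adjusted over the list alone), with Upk1b at 2.94 ± 0.12 and Krt19 at 2.23 ± 0.16 (camera adjusted p = 5.72e-06, and 0.0157 with an estimated correlation). In the imprinted list 12 of 14 genes rose (the same adjusted over the list alone), with Igf2 at 4.50 ± 0.15 and Peg10 at 4.28 ± 0.09 (camera adjusted p = 1.94e-06, and 0.0228 with an estimated correlation). In the cell cycle list 19 of 23 genes rose and 1 fell (the same adjusted over the list alone), with Cdk1 at 1.67 ± 0.08 (camera adjusted p = 7.14e-06, but adjusted p = 0.216 with an estimated correlation).

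In the endothelial list 20 of 20 genes fell (the same adjusted over the list alone) in ES adipocytes, with Emcn at -6.01 ± 0.18 (camera adjusted p = 6.17e-21, and 0.00535 with an estimated correlation). In class II antigen presentation 7 of 8 genes fell (the same adjusted over the list alone), with H2-Aa at -7.52 ± 0.15 (camera adjusted p = 3.9e-07, and 0.00746 with an estimated correlation). In the macrophage list 21 of 21 genes fell (the same adjusted over the list alone), with Lyz2 at -6.67 ± 0.20 (camera adjusted p = 4.53e-17, but adjusted p = 0.216 with an estimated correlation). In the smooth muscle list 7 of 13 genes fell and 1 rose (the same adjusted over the list alone), with Synpo2 at -2.03 ± 0.10 (camera adjusted p = 0.0113, but adjusted p = 0.306 with an estimated correlation). In the preadipocyte list 7 of 15 genes fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 0.0366, but adjusted p = 0.425 with an estimated correlation), among them the progenitor markers Pi16 at -2.64 ± 0.09 and Cd34 at -1.89 ± 0.10. Hprt, a housekeeping enzyme of purine salvage, fell by 5.14 ± 0.14, to 4.45 on the log2 scale.

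Between ES adipocytes and eWAT 9911 genes changed, 5750 higher and 4161 lower. At least 2-fold changes numbered 2043, 875 higher and 1168 lower. The arrays did not overlap for 11552 genes, against 10% by chance, and 15 of 33 lists shifted, 4 up and 11 down. Centring on the reference genes, Hprt included, moved the median by 0.499 and the share of higher calls from 58% to 90.5%, and turned the split of 2-fold changes to 2955 higher and 668 lower. It also turned the medians of the adipocyte (to 0.27), branched-chain (0.23), smooth muscle (0.18) and preadipocyte lists (0.30). Camera, which is relative to all other genes, still passed for the branched-chain, smooth muscle and preadipocyte lists (adjusted p = 0.00232, 0.00109 and 0.00324). The adipocyte list call was lost in that setting (adjusted p = 0.172) and without eWAT array 1 (0.06), and the preadipocyte call without ES array 1 (0.0652), eWAT array 2 (0.0684) or eWAT array 3 (0.0556).

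**Figure D2:**
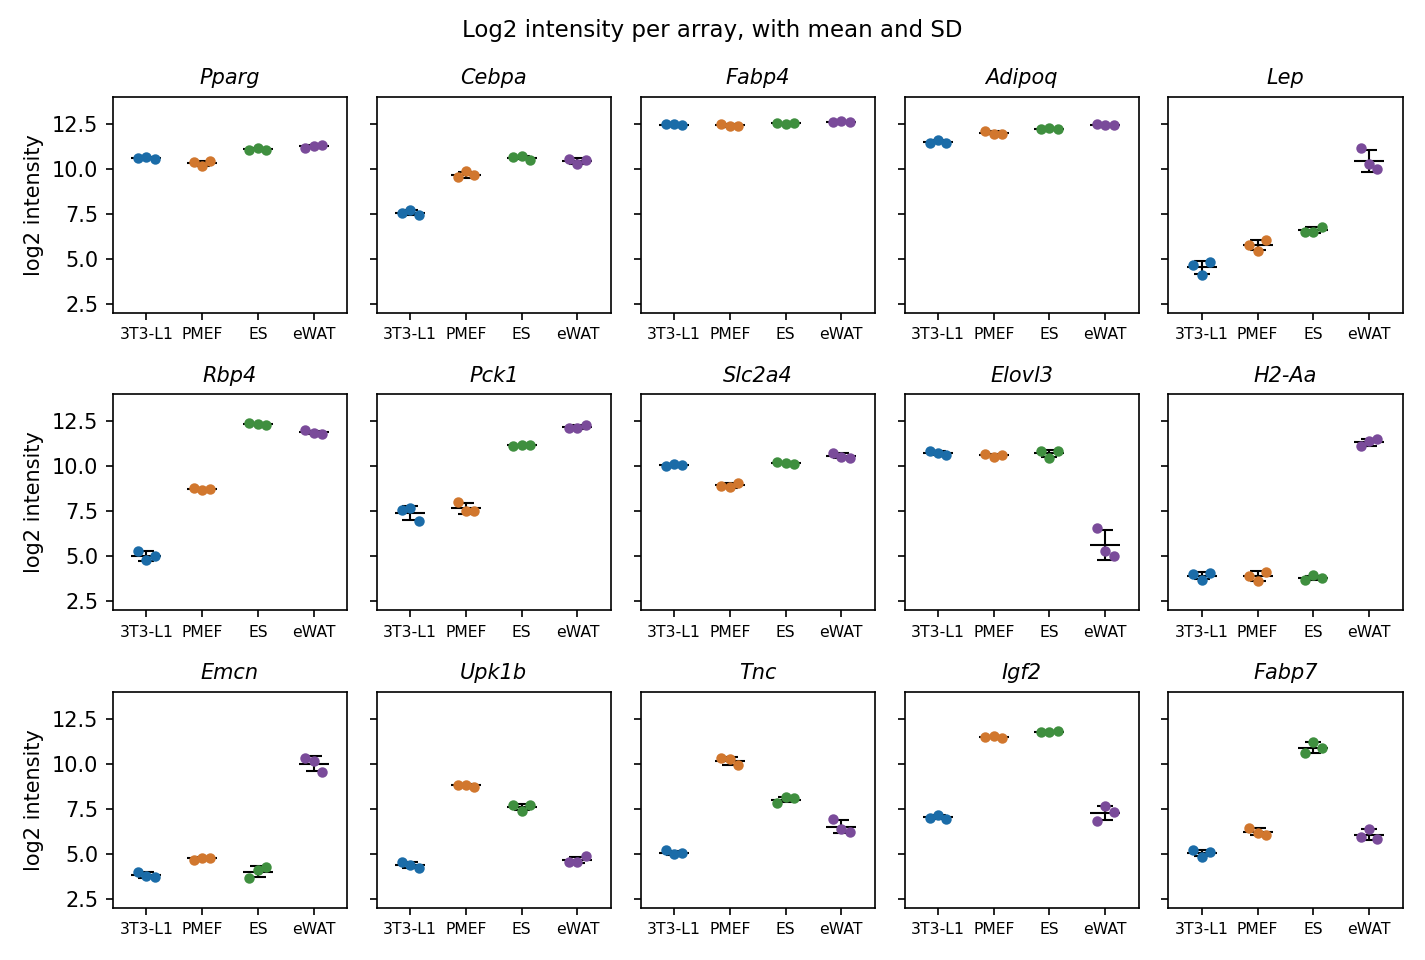
Log2 intensity (vertical axis) of 15 genes in each array, with 1 point per array, by group on the horizontal axis. The black bars are the mean and SD of 3 arrays. Rbp4 and Cebpa are lowest in 3T3-L1 adipocytes, H2-Aa and Emcn are highest in eWAT, and Fabp7 is highest in ES adipocytes.

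Against eWAT, 2059 genes were higher in all 3 models and 2125 were lower in all 3, of which 133 and 712 changed at least 2-fold in each. On the reference genes the lower count was 1333. Elovl3, an enzyme that lengthens fatty acids, was at least 31-fold higher in every model, and the imprinted gene Peg10 at least 6.73-fold. H2-Aa was at least 168-fold lower, Retnla, a secreted product of alternatively activated macrophages, at least 80.1-fold lower and the vessel gene Emcn at least 38.3-fold lower. Independent lists of these sizes would share 438 and 202 genes. Part of the excess can come from the shared eWAT arrays. In opposite directions in different models went 2174 of the 14266 genes called in at least 1 model. Of the lists described, the endothelial and class II lists held with an estimated correlation in all 3 comparisons with eWAT.

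**Figure D3:**
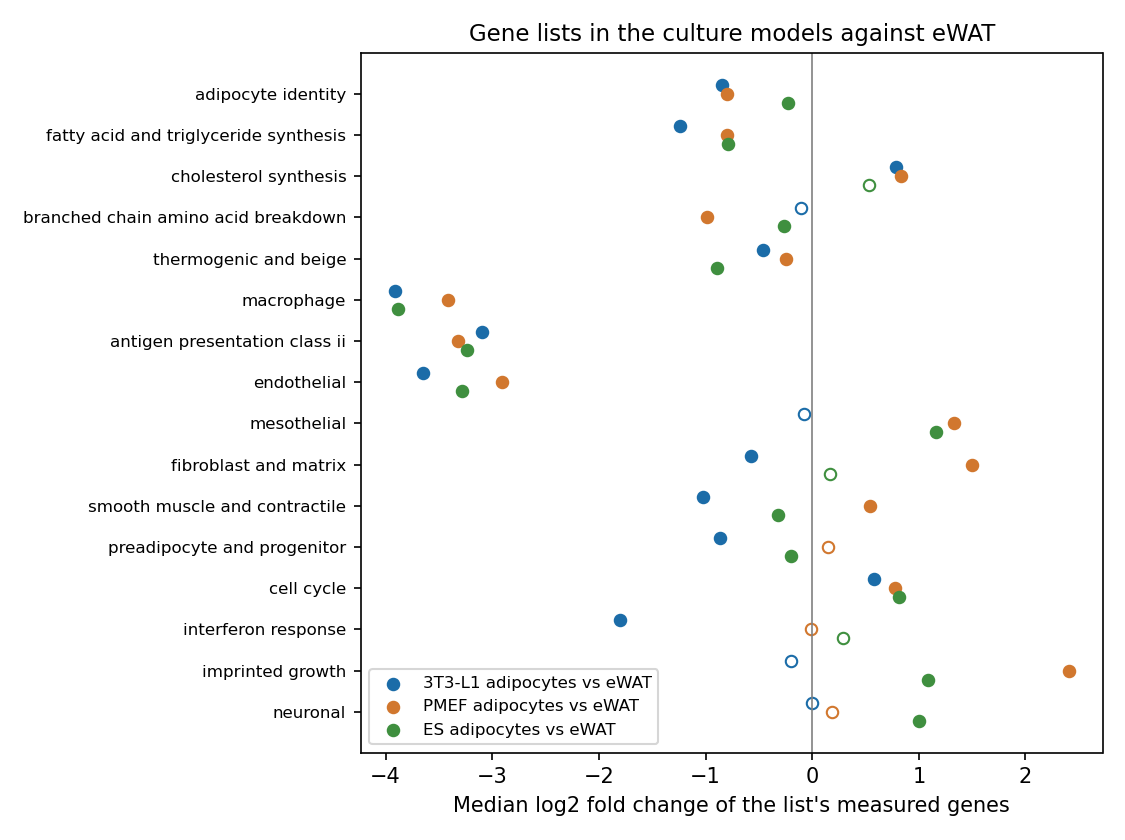
Median log2 fold change (horizontal axis) of the measured genes of 16 gene lists in each culture model against eWAT. Filled points passed camera at an adjusted p under 0.05 and open points did not. The macrophage, class II and endothelial medians lie between -3.92 and -2.91 in all 3 models.

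The models were also compared with each other. PMEF adipocytes had far more transcript of matrix, mesothelial and imprinted genes than 3T3-L1 adipocytes. The Wnt inhibitor Sfrp1 rose by 7.49 ± 0.17, the imprinted growth regulator Grb10 by 5.71 ± 0.07 and Car3, an abundant carbonic anhydrase of fat cells, by 6.71 ± 0.07 (log2, SE, n = 3 per group). Lcn2 fell by 6.16 ± 0.24 and the stress-response factor Atf3 fell by 4.87 ± 0.12.

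The adipocyte list did not shift between PMEF and 3T3-L1 adipocytes, in that 9 of 23 genes rose and 8 fell (the same adjusted over the list alone), with a median of -0.05, a mean of 0.20 and a camera adjusted p of 0.878. Its members parted, since Rbp4 rose by 3.71 ± 0.11 and Cebpa by 2.11 ± 0.11 and Slc2a4 fell by 1.13 ± 0.09. Pparg was at -0.29 ± 0.08 (adjusted p = 0.00803), but did not pass on the reference genes (-0.02 and 0.852, or -0.01 and 0.884 without Hprt) or with quantile normalization (0.0712). In branched-chain amino acid breakdown 15 of 17 genes fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 2.61e-06, but adjusted p = 0.228 with an estimated correlation). Bcat2 and Bckdhb, from the first steps of that pathway, were at -1.74 ± 0.08 and -1.42 ± 0.08.

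In the mesothelial list 13 of 13 genes rose (the same adjusted over the list alone), with Upk1b at 4.40 ± 0.12 (camera adjusted p = 1.12e-07, and 0.0104 with an estimated correlation). In the fibroblast list 19 of 20 genes rose and 1 fell (the same adjusted over the list alone), with the proteoglycan Lum at 5.88 ± 0.08 (camera adjusted p = 4.75e-14, and 0.0104 with an estimated correlation). In the imprinted list 13 of 14 genes rose and 1 fell (the same adjusted over the list alone), with Peg3 at 5.70 ± 0.22 and the noncoding Meg3 at 5.18 ± 0.07 (camera adjusted p = 1.14e-08, and 0.0104 with an estimated correlation). In the smooth muscle list 11 of 13 genes rose and 1 fell (the same adjusted over the list alone), with Myl9 at 4.36 ± 0.16 (camera adjusted p = 2.98e-06, but adjusted p = 0.0825 with an estimated correlation). In the interferon response 15 of 16 genes rose (the same adjusted over the list alone), with Ifit3 at 3.15 ± 0.44 (camera adjusted p = 8.09e-06, but adjusted p = 0.535 with an estimated correlation). In the preadipocyte list 11 of 15 genes rose and 1 fell (12 and 1 adjusted over the list alone), with Cd34 at 5.58 ± 0.10 (camera adjusted p = 1.69e-05, but adjusted p = 0.144 with an estimated correlation), and in the Hox list 18 of 37 genes rose and 6 fell (the same adjusted over the list alone), with Hoxc8 at 5.09 ± 0.09 (camera adjusted p = 0.00384, but adjusted p = 0.314 with an estimated correlation).

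Between PMEF and 3T3-L1 adipocytes 9985 genes changed, 4450 higher and 5535 lower. At least 2-fold changes numbered 2497, 1459 higher and 1038 lower. The arrays did not overlap for 11261 genes, against 10% by chance, and 10 of 33 lists shifted, 9 up and 1 down. The share of higher calls, 44.6%, was 76.6% on the reference genes and 77% without Hprt, with median shifts of 0.276 and 0.28.

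ES adipocytes had higher levels of mesothelial, matrix and imprinted genes than 3T3-L1 adipocytes, and of several single genes of fat cells. Rbp4 rose by 7.32 ± 0.11, Pck1 by 3.76 ± 0.17, Cebpa by 3.04 ± 0.11 and Lep by 2.06 ± 0.26 (log2, SE, n = 3 per group). Fabp7 rose by 5.84 ± 0.17. Hprt fell by 5.86 ± 0.14, and Slc35e3, a putative nucleotide sugar transporter, fell by 4.87 ± 0.09.

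In the adipocyte list 15 of 23 genes rose and 4 fell (the same adjusted over the list alone) in ES against 3T3-L1 adipocytes (camera adjusted p = 8.96e-05, but adjusted p = 0.351 with an estimated correlation). Pparg rose by 0.47 ± 0.08, Adipoq by 0.72 ± 0.07 and Plin1 by 0.91 ± 0.08. In fatty acid and triglyceride synthesis 10 of 21 genes rose and 4 fell (the same adjusted over the list alone), with the lipogenic regulator Srebf1 at 2.51 ± 0.07 (camera adjusted p = 0.0174, but adjusted p = 0.396 with an estimated correlation). In cholesterol synthesis 13 of 18 genes fell and 3 rose (the same adjusted over the list alone), with Idi1 at -1.83 ± 0.09 (camera adjusted p = 0.00567, but adjusted p = 0.438 with an estimated correlation). In the interferon response 16 of 16 genes rose (the same adjusted over the list alone), with a median of 2.47 and Usp18 at 3.46 ± 0.29 (camera adjusted p = 4.7e-09, but adjusted p = 0.351 with an estimated correlation). In the neuronal list 18 of 19 genes rose (the same adjusted over the list alone), with Stmn2 at 2.92 ± 0.21 (camera adjusted p = 7.68e-08, but adjusted p = 0.351 with an estimated correlation). The neural progenitor and glial list (camera adjusted p = 0.0165) and the pluripotency list (0.0264) also shifted up, but neither passed with an estimated correlation. Both calls were lost on the reference genes (0.226 and 0.173). The pluripotency call was also lost with quantile normalization (0.0599) and without the dimmest genes (0.368). In the preadipocyte list 8 of 15 genes rose and 2 fell (the same adjusted over the list alone), with Cd34 at 3.54 ± 0.10 (camera adjusted p = 0.00267, but adjusted p = 0.351 with an estimated correlation). In the mesothelial list 12 of 13 genes rose (the same adjusted over the list alone), with Gpm6a at 3.50 ± 0.17 (camera adjusted p = 1.84e-08, and 0.0136 with an estimated correlation), in the fibroblast list 18 of 20 genes rose and 2 fell (the same adjusted over the list alone), with Lum at 3.28 ± 0.08 (camera adjusted p = 4.7e-09, and 0.0413 with an estimated correlation), and in the imprinted list 13 of 14 genes rose and 1 fell (the same adjusted over the list alone), with Peg3 at 4.93 ± 0.22 (camera adjusted p = 8.21e-09, and 0.0158 with an estimated correlation).

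Between ES and 3T3-L1 adipocytes 8651 genes changed, 4071 higher and 4580 lower. At least 2-fold changes numbered 1623, 1063 higher and 560 lower. The arrays did not overlap for 11046 genes, against 10% by chance, and 14 of 33 lists shifted, 12 up and 2 down. The share of higher calls, 47.1%, was 34.6% with arrays centred on their medians, 96.9% on the reference genes (median shift 0.774, with 4366 higher and 118 lower at least 2-fold) and 75.2% without Hprt (0.209). On the reference genes the calls on fatty acid synthesis (adjusted p = 0.089) and preadipocyte genes (0.173) were lost, and the median of the cholesterol list turned from -0.51 to 0.27. The cholesterol list still passed camera there, which is relative to all other genes (adjusted p = 7.18e-06).

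ES adipocytes had less transcript of matrix genes than PMEF adipocytes, and more of several single genes of fat cells. Rbp4 rose by 3.61 ± 0.11, Pck1 by 3.49 ± 0.17 and Slc2a4 by 1.23 ± 0.09 (log2, SE, n = 3 per group). Lum fell by 2.60 ± 0.08, and the collagen gene Col1a2 was at -2.14 ± 0.08. Xist fell by 6.03 ± 0.09, and the adenylate kinase gene Ak4 rose by 4.65 ± 0.14.

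In the adipocyte list 18 of 23 genes rose and 1 fell (19 and 1 adjusted over the list alone) in ES against PMEF adipocytes (camera adjusted p = 7.64e-07, but adjusted p = 0.18 with an estimated correlation). Pparg rose by 0.76 ± 0.08, Cebpa by 0.94 ± 0.11 and Plin1 by 0.59 ± 0.08. Lep rose by 0.83 ± 0.26 (adjusted p = 0.0199), a call lost without PMEF array 2 (0.68, adjusted p = 0.0871) or ES array 3 (0.73, 0.0706). In branched-chain amino acid breakdown 16 of 17 genes rose (the same adjusted over the list alone), with Bckdhb at 1.57 ± 0.08 and Bcat2 at 1.22 ± 0.08 (camera adjusted p = 3.5e-07, but adjusted p = 0.237 with an estimated correlation). In cholesterol synthesis 11 of 18 genes fell and 2 rose (the same adjusted over the list alone), with Hsd17b7 at -1.66 ± 0.10 (camera adjusted p = 0.000382, but adjusted p = 0.486 with an estimated correlation). In the fibroblast list 18 of 20 genes fell (the same adjusted over the list alone, camera adjusted p = 2.85e-12, and 0.047 with an estimated correlation), and in the smooth muscle list 13 of 13 genes fell (the same adjusted over the list alone), with Acta2, the actin of contractile fibroblasts, at -1.55 ± 0.09 (camera adjusted p = 1.05e-07, but adjusted p = 0.0791 with an estimated correlation). In the imprinted list 10 of 14 genes fell and 1 rose (11 and 1 adjusted over the list alone), with Mest at -1.74 ± 0.12 and Peg10 at 1.53 ± 0.09 (camera adjusted p = 0.000382, but adjusted p = 0.118 with an estimated correlation). In the Hox list 19 of 37 genes fell and 6 rose (20 and 7 adjusted over the list alone), with Hoxc8 at -2.83 ± 0.09 (camera adjusted p = 0.00718, but adjusted p = 0.404 with an estimated correlation). In the neuronal list 13 of 19 genes rose and 1 fell (15 and 1 adjusted over the list alone), with Dcx at 1.57 ± 0.16 (camera adjusted p = 0.000382, but adjusted p = 0.564 with an estimated correlation). The neural progenitor and glial list passed camera (adjusted p = 0.041), but not with an estimated correlation, and its median was only 0.051. That call was lost without PMEF array 1 (0.121), without the dimmest genes (0.0976) and on the reference genes (0.0731). The pluripotency list did not pass camera (adjusted p = 0.995).

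Between ES and PMEF adipocytes 8501 genes changed, 4713 higher and 3788 lower. At least 2-fold changes numbered 1338, 506 higher and 832 lower. The arrays did not overlap for 10450 genes, against 10% by chance, and 12 of 33 lists shifted, 4 up and 8 down. The share of higher calls, 55.4%, was 49.7% with quantile normalization, 48.7% with arrays centred on their medians, 92.5% on the reference genes (median shift 0.498, with 2254 higher and 351 lower at least 2-fold) and 44% without Hprt. On the reference genes the medians of the cholesterol (to 0.05) and Hox lists (0.17) turned. These lists still passed camera there (adjusted p = 9.38e-06 and 3.78e-05). The neuronal call was lost on the reference genes (adjusted p = 0.0625) and without the dimmest 33.3% of genes (0.133).

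Genes that set 1 group apart from each of the 3 others by at least 2-fold numbered 791 for 3T3-L1 adipocytes (266 higher, 525 lower) and 451 for PMEF adipocytes (419 higher, 32 lower). They numbered 168 for ES adipocytes (134 higher, 34 lower) and 845 for eWAT (712 higher, 133 lower). On the reference genes the higher and lower genes set apart were 66 and 933 in 3T3-L1, 236 and 50 in PMEF, and 636 and 7 in ES adipocytes. 3T3-L1 adipocytes stood out by low Car3, the complement inhibitor Serping1 and the secreted peroxidase Gpx3, each at least 58.3-fold lower than in any other group. PMEF adipocytes stood out by Xist, at least 64.5-fold higher, the secreted Egfl6 at 27.8-fold or more and the matrix gene Fmod at 12.9-fold or more. ES adipocytes stood out by Fabp7, at least 25.4-fold higher, and by Ak4, the glycolytic enzyme Aldoc and the oxygen sensor Egln3, each at least 10.2-fold higher. They also stood out by Hprt and the transcript AI506816, at least 35.2-fold and 59.9-fold lower. eWAT stood out by H2-Aa, Retnla and Adgrl4, a receptor of vessel lining, each at least 66.2-fold higher.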

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

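Small log2 changes depended on how the arrays were brought to a common level, and values near background were imprecise on these arrays. Quantile normalization, centring on medians, the mean of a gene's probe sets, array weights and a trended variance left every count of genes, in total or by direction, and every number of lists shifted within 1.5 times. So did the arrays of 2 groups alone, where genes set apart or shared by models were not counted. Among values of named genes under the alternative settings, 3850 kept direction and side of the threshold, 17 fell short of it, 11 newly passed and 6 reversed. Many of these settings cannot alter a fold change, such as a trended variance, the replicate block or leaving out an array of another group. Named genes were also mostly picked for large changes, so the first of these counts says little about robustness. The cause was not tested unless it is given.

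Replicate numbers did not pair the arrays. Deviations from the group means correlated at -0.137 to 0.108 between arrays of the same number, and not every array correlated best with its own number. With the number as a block, 10519, 9009 and 9739 genes changed in 3T3-L1, PMEF and ES adipocytes against eWAT, 9832 in PMEF against 3T3-L1, and 8435 and 8287 in ES against 3T3-L1 and PMEF adipocytes. The block changed no call of a named gene or count of lists.

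The 6 reversed values were those of ES adipocytes against eWAT on the reference genes: Pparg 0.33, Fabp4 0.423, Adipoq 0.267, Retn 0.143, Plin1 0.268 and Slc2a4 0.087. By construction that centring carries the low Hprt of the ES arrays into each of their values. With it 17369 genes changed in ES adipocytes against eWAT (3623 at least 2-fold), 18580 against 3T3-L1 (4484) and 17070 against PMEF (2605). Genes set apart were 286 in PMEF and 643 in ES adipocytes. Distances to eWAT were 0.9722 in 3T3-L1 and 0.8932 in ES adipocytes over all genes, and 2.5664 and 0.9868 over the adipocyte list. Without Hprt, a setting chosen after the data were seen, the 3T3-L1 distances were 0.9571 and 2.5362. Every total stayed within 1.5 times, but the split by direction did not. In 3T3-L1 adipocytes against eWAT, higher calls went from 6146 to 3985 (at least 2-fold, 1207 to 715) and lower calls from 4482 to 8245. In PMEF against 3T3-L1, higher calls went from 4450 to 11020 and lower calls from 5535 to 3291 (1038 to 530). In ES against 3T3-L1, higher calls went from 4071 to 7891 and lower calls from 4580 to 2606 (560 to 355). Genes set apart as higher in 3T3-L1 went from 266 to 151. With Hprt, higher and lower calls went from 6146 to 3579 and 4482 to 9396 in 3T3-L1 against eWAT, 5750 to 15717 and 4161 to 1652 in ES against eWAT, and 4450 to 10739 and 5535 to 3287 in PMEF against 3T3-L1. They went from 4071 to 18001 and 4580 to 579 in ES against 3T3-L1, and 4713 to 15795 and 3788 to 1275 in ES against PMEF. At least 2-fold, higher calls went from 1207 to 653 in 3T3-L1 and 875 to 2955 in ES against eWAT, 1063 to 4366 in ES against 3T3-L1 and 506 to 2254 in ES against PMEF. Lower ones went from 1168 to 668 in ES against eWAT, 1038 to 532 in PMEF and 560 to 118 in ES against 3T3-L1, and 832 to 351 in ES against PMEF. Genes lower in all 3 models went from 2125 to 1333. Genes set apart as higher went from 266 to 66 in 3T3-L1, 419 to 236 in PMEF and 134 to 636 in ES adipocytes, and as lower from 525 to 933, 32 to 50 and 34 to 7.

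After quantile normalization the distances over all genes were 0.9171, 0.7734 and 0.7473 in 3T3-L1, PMEF and ES adipocytes, and over the adipocyte list 2.4661 in 3T3-L1 and 1.0627 in ES adipocytes. Without the dimmest genes the distances over all genes were 1.0609, 0.8521 and 0.8239. With all probe sets tested, which raises the number of tests, 16719 changed in 3T3-L1 adipocytes against eWAT and 15132 in PMEF against 3T3-L1. At least 2-fold changed 4762, 3159 and 3193 in 3T3-L1, PMEF and ES adipocytes against eWAT, 4054 in PMEF and 2701 in ES against 3T3-L1, and 2335 in ES against PMEF. In that setting 16 lists shifted in PMEF against 3T3-L1, and 1200 and 282 probe sets were set apart in 3T3-L1 and ES adipocytes. By direction, 17 of 34 counts were over 1.5 times higher with all probe sets, by 1.51 to 2.84 times. Distances were 0.8697, 0.7204 and 0.6977 over all probe sets and 1.0695 over the adipocyte list in ES adipocytes.

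Treat against a log2 change of 1, a stricter test, called 1828, 1274 and 1118 genes in 3T3-L1, PMEF and ES adipocytes against eWAT, 1579 in PMEF and 955 in ES against 3T3-L1, and 610 in ES against PMEF. In the same order an estimated correlation left 2, 7, 4, 3, 3 and 1 lists, and fry, which tests each list on its own, called 28, 26, 28, 17, 23 and 22.

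With each array left out in turn, genes changed in 3T3-L1, PMEF and ES adipocytes against eWAT ranged over 9922 to 10767, 8264 to 9393 and 8952 to 10098, and between models over 9184 to 10306, 7758 to 9005 and 7455 to 8852. Distances over all genes ranged from 0.9151 to 0.9405 in 3T3-L1, 0.7578 to 0.7733 in PMEF and 0.7346 to 0.761 in ES adipocytes. Over the adipocyte list they ranged from 2.3712 to 2.4397, 1.7126 to 1.7735 and 0.9876 to 1.0501.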

Other observations

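The hypoxia list, the search along chromosomes, and the tests of a mislabelled array and of a copy gain were chosen after results had been seen. The tests of a wider X chromosome loss and of a p53 target response were also prompted by patterns seen in these arrays. Genes that cells switch on when oxygen is short were high in ES adipocytes. Ak4 rose by 4.86 ± 0.14 against eWAT, and the oxygen sensor Egln3 and the glycolytic enzyme Aldoc were also among the genes that set ES adipocytes apart. A list of 36 genes induced by hypoxia was then written without these. Of its genes, 2 were left out because they were already named among genes set apart, and 29 others were measured. Against eWAT 27 of them rose and 1 fell in ES adipocytes, with a median of 1.26 (camera adjusted p = 4.49e-13 over the 6 comparisons, and 0.000252 with an estimated correlation). Against PMEF adipocytes 27 rose and 0 fell (5.97e-18 and 2e-04), and against 3T3-L1 adipocytes 23 rose and 2 fell (3.59e-13 and 0.000252). Among members chosen after their values were seen, the glucose transporter Slc2a1 was at 3.20 against eWAT in ES adipocytes. The lactate carrier Slc16a3 was at 2.94, the collagen enzyme Plod2 at 3.52 and Ero1a at 4.02. Some of these were high in another model too, with Slc2a1 at 2.39 and Ero1a at 4.13 in 3T3-L1 and Plod2 at 2.795 in PMEF adipocytes. Slc16a3 was at -0.289 and -0.204 in 3T3-L1 and PMEF adipocytes. In 3T3-L1 against eWAT 12 rose and 11 fell (0.726). In PMEF adipocytes more genes fell than rose, 11 against 6 compared with eWAT and 16 against 8 compared with 3T3-L1 adipocytes (0.184 each, and 0.26 each with an estimated correlation). No explanation was tested.

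Some neighbouring genes moved as blocks, by the median of 11 adjacent genes against the mean of the other groups. The imprinted stretch of chromosome 12 from Rian to Mir329 was at 2.28 in PMEF adipocytes and at -1.60 in 3T3-L1 adipocytes, where the largest medians in 100 shuffles of gene order were 1.17 and 1.48. In this stretch 30 windows passed in PMEF adipocytes and 1 in 3T3-L1 adipocytes. The mean set against 3T3-L1 holds the high PMEF values, which lowers the 3T3-L1 value. Protocadherin genes from Pcdhb2 to Pcdhb12 were higher in ES adipocytes by more than the 0.892 seen in shuffles. In eWAT the immune gene clusters from Ms4a12 to Ms4a6d and from Mcemp1 to Cd209g were at 1.98 and 1.68 (1.46 in shuffles). Neighbouring genes are not independent, so the shuffles are only a rough yardstick. Among sex-linked genes, PMEF adipocytes held Xist at 10.06 together with the Y-linked Eif2s3y at 8.57, Eif2s3y was at 3.47 in 3T3-L1 adipocytes, and in ES adipocytes it was at 9.32 against 9.30 in eWAT. Kdm5d of the Y chromosome fell by 2.66 ± 0.14 in ES adipocytes against eWAT, while the other 3 measured genes of the sex-linked list did not pass. No explanation was tested for these patterns.

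Hprt lay near background in ES adipocytes, at 4.45 against 9.59 to 10.31 in the other groups. Loss of an X chromosome stretch with most of the 5 nearest expressed genes on each side would have lowered their median difference. It was -0.045 (25th to 75th percentile -0.329 to 0.175), which argues against a loss that wide. The nearest gene before Hprt, Gpc3, was at 2.748, and the nearest after it, Mospd1 and Rtl8c, were at -0.53 and -1.376. A loss reaching only a few neighbours was not excluded. In 3 of 3 ES arrays Hprt lay below every other array, which 1 mislabelled array would not give. The ES line is not named in the labels, and whether it lacked a working Hprt gene was not tested.

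Slc35e3 and its neighbour Mdm2 were high in 3T3-L1 adipocytes, by 4.99 and 3.49 against the mean of the other groups. A copy gain reaching the neighbouring genes would have raised the 3 nearest genes on each side that were expressed in every group, and their median difference was 0.185 (25th to 75th percentile 0.09 to 0.356). Single differences ran from 0.036 to 0.513. The test asked for a 25th percentile above a log2 difference of 1, so it could not exclude a gain with a smaller effect. A p53 target response would have raised the other targets of p53, and the median of 22 of them was -0.23 (75th percentile 0.126). Single targets ran from -2.255 for Phlda3 to 1.648 for Plk2. The same rule was used, so a response of only some targets was not excluded. A gain limited to these 2 genes was not tested, nor was a biological explanation.

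The share of fat cells in each culture was not measured here, and its part in the lower adipocyte genes of the models was not tested.

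Groups were also redrawn. In the 10 splits of the 6 arrays of each comparison, only the real split, 1 of 10, gave as many genes changed, or changed at least 2-fold, and the highest other count was 0 in all 6 comparisons. For gene lists shifted, the real values and the highest others were 16 and 13 in 3T3-L1 adipocytes vs eWAT (1 split as large), 14 and 17 in PMEF adipocytes vs eWAT (6), 15 and 14 in ES adipocytes vs eWAT (1), 10 and 12 in PMEF adipocytes vs 3T3-L1 adipocytes (6), 14 and 9 in ES adipocytes vs 3T3-L1 adipocytes (1), and 12 and 12 in ES adipocytes vs PMEF adipocytes (3). With 10 splits none can reach a share under 0.05. In 100 splits of all 12 arrays, 4184 genes changed the same way in all 3 models vs eWAT, against at most 2442 in another split (1 as large). Genes set apart in 3T3-L1 adipocytes were 791, with 882 the highest other (2 as large), genes set apart in PMEF adipocytes 451 and 867 (3), genes set apart in ES adipocytes 168 and 0 (1), and genes set apart in eWAT 845 and 856 (2). The numbers as large include the real split. A redrawn split can keep the 3 arrays of a real group together under another group's name. Large counts can arise that way, so these splits do not measure how often chance gives such a result.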
